A study of Nitratidesulfovibrio vulgaris str. Hildenborough with 30 samples.

How the data were processed

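Transcript levels of Desulfovibrio vulgaris Hildenborough, an anaerobic sulfate-reducing bacterium, were measured on 30 arrays of 2 colours. Per the labels, cells grew in batch culture in the defined medium LS4D, and total RNA carried Cy5 while genomic DNA of the same strain carried Cy3 and served as the common reference on every array. RNA extraction and labelling are cited in the labels to an oligonucleotide probe design study. The labels place the arrays in 10 groups of 3: cells treated with 250 mM KCl and untreated cells, each at 0, 30, 60, 120 and 240 min. They number the replicates but do not say whether these came from separate cultures, so the p-values measure the spread between these samples, which may be partly technical. No slide, date or hybridisation batch is given in the sources used here, so no batch could be tested.

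The authors deposited 1 log ratio per spot and array, read here as log2. The base of the logarithm is not given in the sources used here: ranges of 11.6 to 14.7 within an array exclude log10 but leave a natural logarithm open, in which case fold thresholds would be understated. Image analysis, background correction and normalization are likewise not given in the sources used here. The medians of the deposited arrays ran from -2.22 to -0.48, so the arrays had not been brought to a common centre. Which channel is the numerator is not stated either. RNA over genomic DNA is the likely direction, on 3 grounds: the labels name RNA as the first channel, the ratios were skewed towards high values on all 30 arrays (skewness 0.54 to 0.91), as few abundant transcripts over an even DNA reference would give, and copies of a spot differed more at the low end, with a median SD of 0.36 in the 10% of spot pairs with the lowest ratios and 0.24 in the ninth class of 10, though 0.27 in the highest. If the ratio runs the other way, "higher" and "lower" change places in every comparison of groups, with the same numbers called and the same sizes of change. Values that single out low ratios or rises would change in meaning: the filter on the lowest mean ratios, the grouping by level and the test of a mixture of RNA.

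The table identifies spots by number, from 1 to 9216, and the sources used here pair no spot number with a gene. The reference table of 3339 genes carries no spot numbers, so no spot was given a gene name, and none was inferred from its order. The 28 gene lists fixed in advance could therefore not be applied, nor the set tests on them or the check of the ratio's direction on ribosomal and sulfate reduction genes. All results are given for spots.

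Spots whose numbers differ by 4608 behaved as copies of 1 probe. Their mean log ratios correlated at r = 0.995 over 3308 couples, against 0.56 at the next highest offset searched, 6912. Each such couple is called a spot pair and is named by its lower number. Every array was centred on its median, and the values of the 2 copies were averaged, or the single value kept where 1 copy had none. A spot pair was tested if at least 2 arrays in each of the 10 groups gave a value. Of 4608 spot pairs, 3572 had a value on at least 1 array and 3205 were tested. The filter that left spots without a value before deposit is not given in the sources used here, and 2139 spots had none on any array. The deposited ratios carry no intensity or background, so the signal behind each value is unknown, and the number of arrays limits the precision.

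A linear model with 1 mean per group was fitted to all 30 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, so that every contrast shared 1 estimate of the spread (20 residual degrees of freedom, 7.11 prior degrees of freedom). The contrasts were KCl minus untreated at each time, the KCl effect at 240 min minus that at 30 min, an F test of the effects at the 4 later times minus the effect at 0 min, and untreated cells at 240 min minus untreated cells at 0 min. P-values were adjusted by Benjamini-Hochberg within a contrast, and an adjusted p under 0.05 is called changed. For spot pairs with missing values, limma's standard errors of contrasts are approximate. These tests, the threshold and the settings to be varied were fixed before the data were examined, for genes, and were applied to spot pairs. The contrast of KCl-treated cells at 240 min with those at 0 min and the successive steps of each course were added later.

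The naming rule took, at each of the 4 later times, the 10 spot pairs with the largest rise and the 10 with the largest fall among those changed whose arrays of the 2 groups did not overlap. It took 5 each way for the other contrasts (with no requirement on overlap for the difference between 240 and 30 min), and none qualified at 0 min. Since the spots carry no gene names, only the 2 spot pairs in each direction that met the rule at the most times are named, ties going to the larger mean change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

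The fit was tested on simulated data with the means of untreated cells at 0 min and the residual spread and missing values of the real arrays, in which at each time 67 spot pairs were changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. For the 0 min comparison it recovered 49.3% of the changes of 0.5, 94.0% of those of 1 and 100% of those of 2, and 5.26% of its calls were false. For the 30 min comparison it recovered 41.8%, 89.6% and 98.5% of these sizes. Recovery of the changes of 0.5 was lowest for the 240 min comparison, at 35.8%. For the 120 min comparison 8.38% of the calls were false, the highest share among the 5 times. The simulated noise was normal, independent between spot pairs and of the same spread on all arrays. Far fewer spot pairs were changed than the 37.8% to 50.0% called in the real comparisons after 0 min. These shares therefore describe the fit under its own assumptions and are not error rates of the real comparisons.

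The alternatives were the values as deposited, quantile normalization, spot pairs with a value on all arrays, no filter on missing values, removal of the 25% of spot pairs with the lowest mean ratio, only the arrays of the groups compared, eBayes with trend and robust estimation, array weights, the replicate number as a block, the treatment and replicate number as a random block, and leaving out each array in turn. Added after seeing the data were centring on spots with a value on all arrays, centring first copies and second copies separately, each copy alone, and leaving out 2 arrays at 30 min together.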

Results

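The study compared gene expression in Desulfovibrio vulgaris Hildenborough after addition of 250 mM KCl, a salt stress, with untreated cells over 240 min. Each of the 30 arrays set total RNA of 1 sample against genomic DNA of the strain, with 3 arrays per treatment at 0, 30, 60, 120 and 240 min. Between 5732 and 6861 of the 9216 spots had a value on an array. Expression is given as the log2 ratio, likely RNA over genomic DNA, centred on the median of the array. The log base and the direction of the ratio are not given in the sources used here, so "higher" and "lower" rest on that direction. The 3205 tested items are spot pairs, each the mean of the 2 copies of a probe, and they are identified by spot number because no probe was paired with a gene.

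Arrays of a group correlated at r = 0.956 to 0.994 across the 3205 tested spot pairs. The median SD between replicates of a spot pair ran from 0.13 in untreated cells at 120 min to 0.24 in KCl-treated cells at 240 min. In a principal component analysis of the 2955 spot pairs with a value on all arrays, the first component held 53.8% of the variance and the second 12.7%. All 12 arrays of KCl-treated cells after 0 min lay at or above 4.41 on the first component, and all 18 other arrays at or below -9.11. At 30 min 2 arrays stood apart from their groups. KCl replicate 1 lay at 4.41 on the first component, where the other 2 lay at 15.8 and 16.8, and untreated replicate 3 lay at -1.72 on the second, where the other 2 lay at 9.61 and 7.16.

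**Figure D1:**
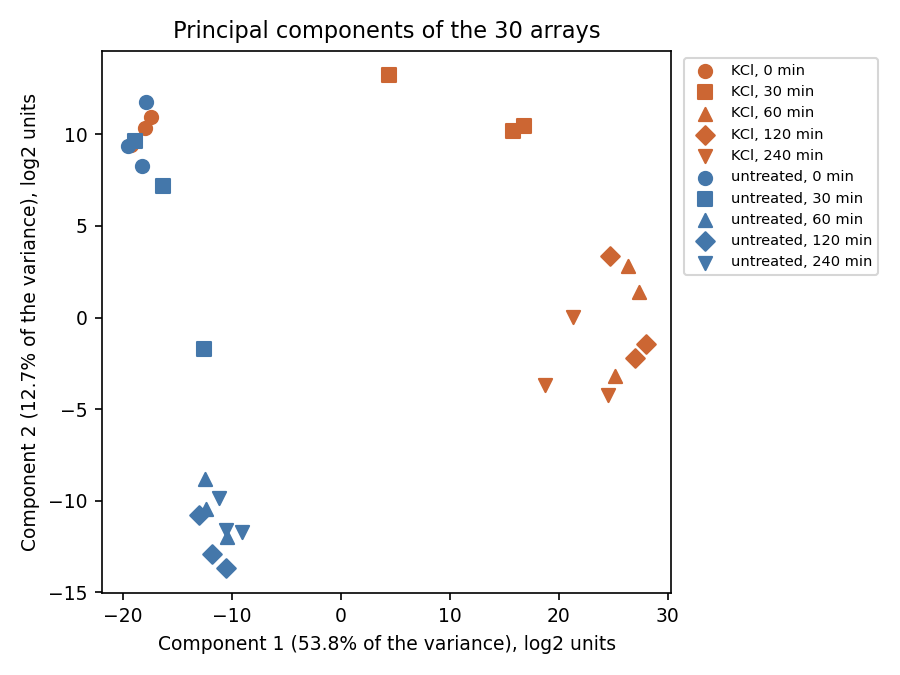
Scores of the 30 arrays on the first (horizontal) and second (vertical) principal component of the centred log2 ratios of 2955 spot pairs; colour marks the treatment, the symbol marks the time, and each point is 1 array. Arrays at 0 min of both treatments lie together, and the KCl arrays from 30 min on lie to the right, at or above 4.41 on the first component.

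The comparison at 0 min asked whether the cultures differed before the salt could act. No spot pair differed between KCl-treated and untreated cells. The lowest adjusted p of limma was 0.587, and 38 spot pairs had an unadjusted p under 0.05, where chance would give 160. Estimated differences ran from -0.77 to 0.96, with an SD of 0.15 across spot pairs and a median standard error of 0.17. Spot pairs 140 and 1264, which met the naming rule for rises at all 4 later times, stood at 0.51 ± 0.19 and 0.34 ± 0.12 in cells of the KCl group (SD, n = 3) and at 0.33 ± 0.19 and 0.28 ± 0.11 in untreated cells. Leaving out KCl replicate 2 gave 1 changed spot pair.

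At 30 min, 1211 of the 3205 spot pairs (37.8%) had changed, 650 higher and 561 lower in KCl-treated cells. Rises of at least 2-fold were found in 198 spot pairs and falls of that size in 93. The largest rise was 4.08 and the largest fall -2.17 on the log2 scale. Spot pair 140 (spots 140 and 4748) rose from 0.27 ± 0.32 in untreated cells to 4.05 ± 0.22 in KCl-treated cells (SD, n = 3), a change of 3.77 ± 0.28 (SE) with an adjusted p of 5.63e-11 in limma. Spot pair 1264 (spots 1264 and 5872) rose by 3.61 ± 0.27, with an adjusted p of 6.76e-11 in limma. Among the falls, spot pair 4489 (spots 4489 and 9097) went from 2.26 ± 0.08 to 0.46 ± 0.40, a change of -1.81 ± 0.21, and spot pair 3330 (spots 3330 and 7938) changed by -1.88 ± 0.40. All 3 KCl arrays lay beyond all 3 untreated arrays for each of these 4. The 10 largest rises of the naming rule lay between 2.70 and 4.08, and the 10 largest falls between -1.52 and -2.17. With the values as deposited the count was 524, with 198 higher and 326 lower, and the median of all spot pairs then shifted by -0.19 with KCl at 30 min, by -0.29 at 60 min, by -0.08 at 120 min and by -0.34 at 240 min. All changes are stated relative to the median of the spots with a value on an array. That set varied between arrays, from 5732 to 6861 spots. After this centring the median change of the tested spot pairs was -0.01, 0.10, 0.07 and 0.06 at 30, 60, 120 and 240 min.

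At 60 min 1604 spot pairs (50.0%) had changed, 958 higher and 646 lower, and at 120 min 1586 (49.5%), 912 higher and 674 lower. Rises of at least 2-fold numbered 338 and 341 at these times and falls 171 and 188. The effects at the 2 times correlated at r = 0.88 across spot pairs, which are not independent replicates. Of the calls, 709 were higher and 473 lower at both times, where independent lists would share 273 and 136. Spot pair 140 changed by 3.89 ± 0.28 at 60 min and 4.03 ± 0.28 at 120 min, and spot pair 1264 by 3.30 ± 0.27 and 3.09 ± 0.27. The fall of spot pair 4489 measured -2.09 ± 0.21 and -2.24 ± 0.21. Spot pair 3330 showed the largest fall of all at 60 min, from 1.49 ± 0.15 in untreated cells to -1.30 ± 0.90 in KCl-treated cells (SD, n = 3), with an adjusted p of 1.58e-06 in limma. The ranges of the 10 largest rises were 2.98 to 3.91 at 60 min and 2.83 to 4.03 at 120 min, and those of the 10 largest falls -2.02 to -2.80 and -2.09 to -2.67. As deposited, 1050 spot pairs were called at 60 min, 270 higher and 780 lower, and 866 at 120 min, 392 higher and 474 lower. The order of the times by count was not tested and did not hold in every fit: array weights gave 1729, 1675, 2023 and 1964 at 30, 60, 120 and 240 min.

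**Figure D2:**
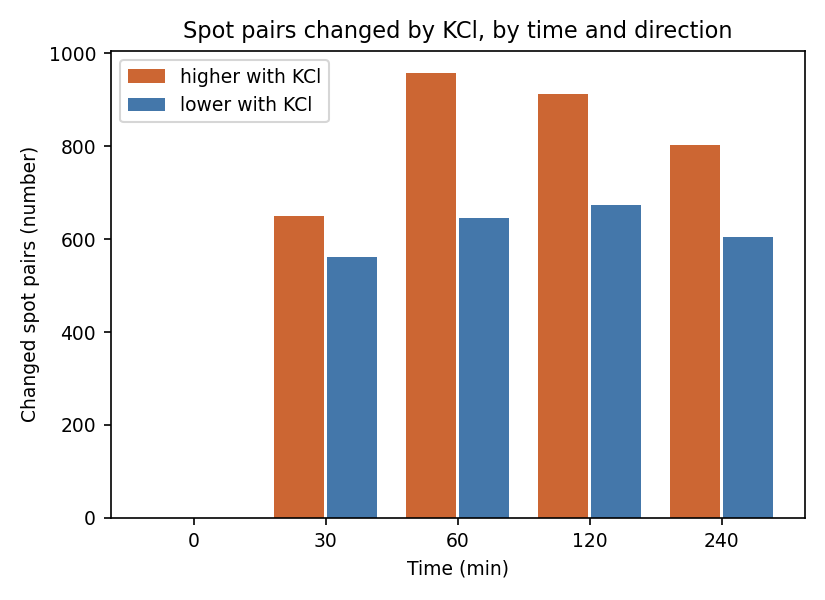
Number of spot pairs (vertical axis) with an adjusted p under 0.05 between KCl-treated and untreated cells at each time in min (horizontal axis), 3 arrays per group; bars give those higher and those lower with KCl. No bar stands at 0 min, and the highest bars are 958 higher at 60 min and 674 lower at 120 min.

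At 240 min 1409 spot pairs (44.0%) still differed, 804 higher and 605 lower, with 280 rises and 132 falls of at least 2-fold. Spot pair 140 stood at 4.28 ± 0.75 in KCl-treated cells and 0.18 ± 0.21 in untreated cells (SD, n = 3), a change of 4.10 ± 0.28 that was the largest at this time. Spot pair 1264 changed by 2.96 ± 0.27 and spot pair 4489 by -2.64 ± 0.21, the largest fall. Spot pair 3330 no longer differed, at -1.49 ± 0.44 with KCl and -1.22 ± 1.13 without (SD, n = 3) and an adjusted p of 0.619 in limma. The sign of this difference of -0.27 was not fixed: it was -0.92 without untreated replicate 2, with an adjusted p of 0.0426 in limma, 0.10 without untreated replicate 3 and 0.25 with array weights. The 10 largest rises lay between 2.70 and 4.10, and the 10 largest falls between -1.99 and -2.64. As deposited, 978 spot pairs were called, 214 higher and 764 lower.

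**Figure D3:**
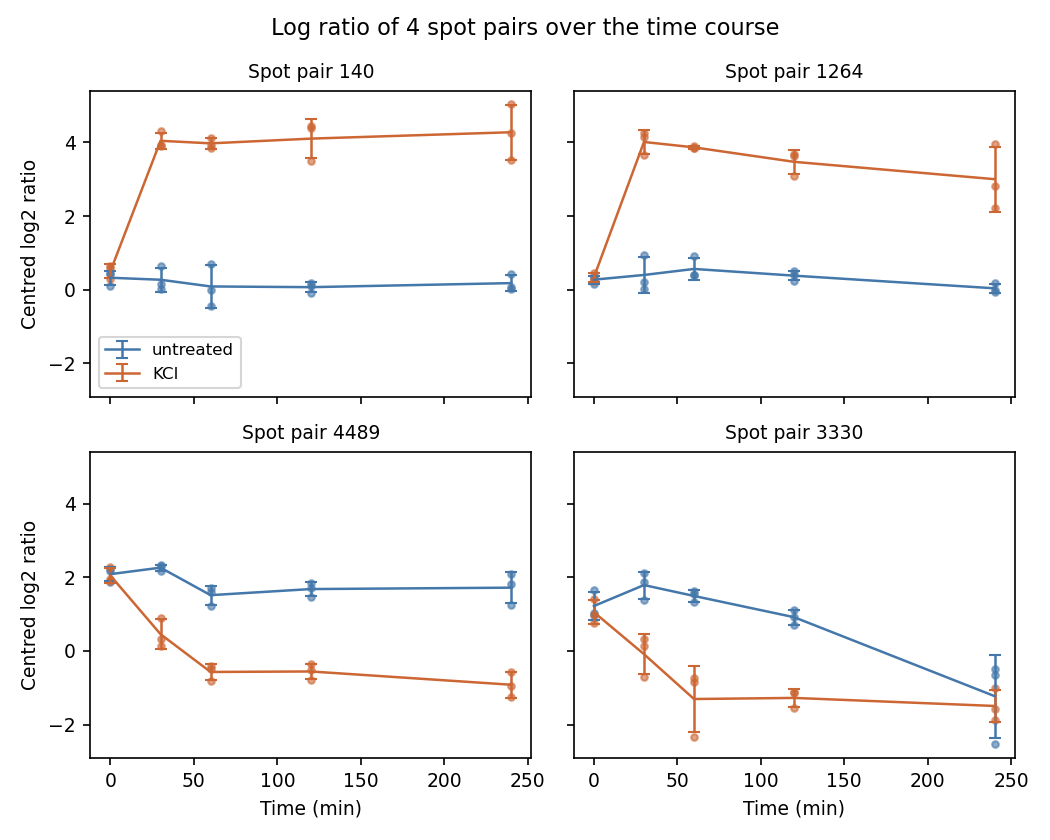
Centred log2 ratio (vertical axis) of spot pairs 140, 1264, 4489 and 3330 against time in min (horizontal axis) in KCl-treated and untreated cells; points are single arrays, and lines join group means with bars of 1 SD, n = 3. Spot pair 140 stays between means of 3.98 and 4.28 with KCl from 30 min to 240 min, and the lines of spot pair 3330 lie at means of -1.49 with KCl and -1.22 without at 240 min.

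Over the 4 later times, 2389 spot pairs changed at least once and 816 at no time. A group of 383 was higher at all 4 times, with a median change of 1.21 at 120 min, and 232 were lower at all 4 times, with a median of -0.97. Both directions at different times were found in 56. Of the spot pairs that had risen at 30 min, 434 were also higher at 240 min, and of those that had fallen, 281 were also lower, where independent lists would share 163 and 106. The correlation of the effects across spot pairs was 0.83 between 30 and 60 min, 0.85 between 120 and 240 min, and 0.65 between 30 and 240 min. Over the 4 times the naming rule took 23 different spot pairs that rose and 25 that fell, 11 and 11 of them at more than 1 time. Spot pairs 140 and 1264 met it for rises at all 4 times, and spot pair 4489 for falls at all 4. With the values as deposited, 82 spot pairs were higher at all 4 times, and with the second copy of each probe alone 131 were lower at all 4.

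The early and the late response were compared through the KCl effect at 240 min minus that at 30 min. This difference was called in 448 spot pairs, 243 with a higher and 205 with a lower effect at 240 min. In 94 of them the rise at 240 min was larger than at 30 min, and in 74 a rise at 240 min went with an estimate at or below 0 at 30 min. Falls grew in 69 and appeared late in 64. Rises called at 30 min were smaller or gone at 240 min in 77, and falls in 90. The call turned from higher to lower in 10 and from lower to higher in 23, and each of these spot pairs is counted in 2 of the classes. The 5 largest positive differences ran from 2.53 to 2.94 and the 5 largest negative ones from -1.86 to -2.65. None of the 4 named spot pairs passed this test, with adjusted p in limma of 0.640 for spot pair 140, 0.278 for 1264, 0.0599 for 4489 and 0.0554 for 3330, at differences of 0.32, -0.65, -0.83 and 1.61. The count depended on the fit: it was 61 (11 higher, 50 lower) as deposited, 254 with only the arrays of the 4 groups, 287 with the second copy of each probe alone and 1225 with array weights. So did its direction: of the differences called, 46.7% were higher without KCl replicate 1 at 30 min, and 45.9% without both arrays at 30 min that stood apart, against 54.2%.

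To set aside any difference already present at 0 min, the effects at the 4 later times were each taken minus the effect at 0 min and tested together. This F test called 1410 spot pairs (44.0%). Taken one time at a time, the differences numbered 639 at 30 min, 1062 at 60 min, 1096 at 120 min and 912 at 240 min, with 367, 648, 648 and 535 of them positive. The F test called 537 with the values as deposited and 2187 with array weights.

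Untreated cells also changed during the experiment, which is the background of the KCl course. Between 0 and 240 min 900 spot pairs changed in them, 497 higher and 403 lower at 240 min, with 83 rises and 46 falls of at least 2-fold. The largest rise was 1.99 and the largest fall -3.10. Among the 5 largest falls was spot pair 3330, which changed by -2.45 ± 0.40 with an adjusted p of 7.03e-05 in limma, from 1.22 ± 0.38 to -1.22 ± 1.13 (SD, n = 3). Spot pairs 140, 1264 and 4489 did not pass the threshold in untreated cells, at -0.15, -0.23 and -0.37. KCl-treated cells changed in 1738 spot pairs over the same interval, 1034 higher and 704 lower. Of these, 321 rose and 224 fell in both courses, where independent lists would share 160 and 88.5, and 25 and 41 moved in opposite directions, where 109 and 130 would. The changes of the 2 courses, which share no array, correlated at r = 0.50 across spot pairs (Spearman's rho 0.49). As deposited, the untreated course had 40 higher and 618 lower, and the KCl course 125 higher and 2061 lower. Each copy was also fitted alone, on arrays centred over both copies. The untreated course then had 695 higher and 193 lower on the first copies and 162 and 477 on the second. The median difference between first and second copies moved between these groups, from -0.30 to -0.23 at 0 min to -0.12 to 0.13 at 240 min. With the copies centred separately before averaging, 916 were called and 55.7% of them were higher, against 55.2%.

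In KCl-treated cells 1420 spot pairs changed between 0 and 30 min, 658 between 30 and 60 min, 182 between 60 and 120 min and 246 between 120 and 240 min. In untreated cells the numbers were 70, 394, 17 and 222. The untreated step from 0 to 30 min gave 55 higher and 15 lower, and that from 30 to 60 min 190 higher and 204 lower. These counts were not compared by a test, and the 30 min steps include the 2 arrays that stood apart. Without both, the 4 steps gave 1549, 476, 301 and 307 in KCl-treated cells and 31, 728, 41 and 277 in untreated cells.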

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

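The tests of a swap and of compressed ratios on the KCl array, and both tests on the untreated array and the test of a mixture with the ratio turned, were chosen after the results were seen; the tests of a mixture, of an earlier stage and of other splits of the arrays were not.

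The KCl effect differed between 240 and 30 min in 448 spot pairs by a test of the difference itself. Of 100 relabellings of treated and untreated arrays within the times, 10 gave a count as large, the real one included, with 940 as the highest other, so chance cannot be excluded by this count. In 9 of the 10, most labels were exchanged at 1 of the 2 times, which turns the difference between the times into a sum and points to a structure of the samples, the treatment effect itself. Of the 99 other relabellings 40 were of that kind, and the highest count among the 59 that were not was 437. The effects after 0 min differed from that at 0 min in 1410 spot pairs, and 1 of 100 relabellings, the real one, gave as many (highest other 1288), so a chance split of the arrays is excluded there.

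For comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 0 and 1 at 0 min, 1211 and 470 at 30 min, 1604 and 0 at 60 min, 1586 and 0 at 120 min, and 1409 and 0 at 240 min. They were 900 and 2 for the untreated course and 1738 and 2 for the KCl course. At 0 min all 10 splits gave a count as large as the real 0, and in each of the others 1 split did. The split with 470 at 30 min set KCl replicate 1 with untreated replicates 1 and 2, so that the 2 arrays that stood apart fell on opposite sides.

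Outside the tests, 356 spot pairs had too few values in some group but a value on some array after 0 min. One of them gave a value on 9 of 12 KCl arrays and on 0 of 12 untreated arrays (Fisher's exact test, two-sided, adjusted p = 0.0399), with a mean centred log2 ratio of 3.33 where it was present. In the other direction 2 passed the threshold, with values on 0 of 12 KCl and 9 of 12 untreated arrays, and on 2 of 12 and 12 of 12. Why values are missing is not given in the sources used here.

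KCl replicate 1 at 30 min lay at 0.521 on an axis from untreated cells (0) to KCl-treated cells at 60 to 240 min (1), where replicates 2 and 3 lay at 0.764 and 0.792. A swap with an untreated array is argued against, since the highest untreated array at 30 min lay at 0.0242, and compressed ratios likewise, since the SD over unchanged spot pairs was 1.03 times that of the other replicates. RNA mixed from treated and untreated cells would have weakened falls more than rises, but the share of the falls reached exceeded the prediction of a mixture by 0.240 (bootstrap SE 0.0293), and by 0.286 (SE 0.0336) with the ratio turned. An earlier stage of the response would leave spot pairs that still grew to 60 min further behind, and these had reached a share larger by 0.0816 (SE 0.0328). They numbered 73, against 246 that did not grow. The bootstraps resampled spot pairs as if independent, so these SEs may be too small and do not measure the spread between arrays. The untreated origin at 30 min included the replicate that stood apart. The array also had fewer spots with a value, 5954 against 6592 and 6643 for replicates 2 and 3. Its median difference between first and second copies was 0.04, against -0.25 and -0.29. KCl replicate 1 at 60 and 240 min also had high values, 0.01 and 0.14. On the first principal component these 2 arrays lay at 25.1 and 24.5. The others of their groups lay at 26.4 and 27.3 at 60 min and at 21.3 and 18.7 at 240 min. Whether the number of values or the copy difference bears on the position of the 30 min array was not tested. A weaker exposure of that culture may be an explanation and was not tested either.

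Untreated replicate 3 at 30 min lay at 0.594 on an axis from untreated cells at 0 min (0) to 120 min (1), where replicates 1 and 2 lay at 0.105 and 0.232. A swap with a 60 min array is argued against, since the lowest of those lay at 0.745. Later sampling and a culture of another history cannot be told apart, because the labels hold no record of sampling. Without both arrays the count at 30 min was 1318 and that of the difference between 240 and 30 min 553, of which 45.9% were higher.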

How the results depend on the processing

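The settings that use a single copy, other centring spots, separate centring of the copies or the removal of 2 arrays at 30 min were chosen after seeing the data. Of 324 values of the 4 named spot pairs after 0 min under the alternatives, 319 kept their direction and side of the threshold. The other 5 were all of spot pair 3330 at 240 min, which was not called at -0.27: array weights gave 0.25, the first copies alone 0.0229, and leaving out single arrays -0.92, which was called, to 0.10. At 0 min, where none of the 4 was called, the values as deposited gave 0.14 for spot pair 4489, against -0.04, and 0.0137 for 3330, against -0.17. Leaving out single arrays there gave -0.00278 to 0.11 for 1264, -0.16 to 0.0335 for 4489 and -0.35 to 0.0522 for 3330. At 0 min every alternative gave 0 changed spot pairs, and leaving out single arrays gave 0 to 1. With the values as deposited, counts fell to 524 at 30 min, 1050 at 60 min, 866 at 120 min, 61 for 240 minus 30 min and 537 for the F test; the cause was not tested. Array weights gave 1225 for 240 minus 30 min and 2187 for the F test; the cause was not tested. The difference between 240 and 30 min was called in 254 spot pairs with only the 12 arrays compared and in 287 with the second copy alone. Neither cause was tested. The other alternatives kept each of these counts, and those at 240 min and of the untreated course, within 1.5 times. Fits to only the arrays compared moved counts both ways. They gave 933, 1533, 1749 and 1158 at 30, 60, 120 and 240 min, against 1211, 1604, 1586 and 1409. For the untreated course the count was 992, against 900. Leaving out single arrays gave 901 to 1286 at 30 min, 1420 to 1500 at 60 min, 1373 to 1471 at 120 min, 1207 to 1388 at 240 min, 319 to 584 for 240 minus 30 min, 1238 to 1537 for the F test and 627 to 753 for the untreated course.

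The split of the calls moved too. Quantile normalization put the share of higher calls at 46.7%, 49.8%, 49.9% and 50.1% at 30, 60, 120 and 240 min, against 53.7%, 59.7%, 57.5% and 57.1%. Centring on the spots with a value on all arrays gave 54.3%, 53.6%, 55.5% and 56.5% at these times. In the untreated course it gave 60.3%, against 55.2%. The first copies alone gave 605 higher and 788 lower at 120 min and the second copies 989 and 409; for the untreated course they gave 695 and 193, and 162 and 477. The median difference between first and second copies ran from -0.33 to 0.14 across arrays, and it differed between groups that were compared. At 120 min it was -0.33 to -0.30 on KCl arrays and -0.13 to 0.10 on untreated arrays. In untreated cells it was -0.30 to -0.23 at 0 min and -0.12 to 0.13 at 240 min. Centring the copies separately before averaging gave 57.8% higher at 120 min, against 57.5%, and 55.7% in the untreated course, against 55.2%.

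With a replicate block the counts were 1248, 1622, 1590 and 1425 at 30 to 240 min, 473 for 240 minus 30 min, 1440 for the F test and 921 for the untreated course. The numbers did not mark pairs: deviations of arrays with the same number at a time correlated from -0.24 to 0.44, 5 of 15 over 0.1, and 7 of 30 arrays correlated best with their own number. The median over 2 copies equals their mean and was not run. The sign of the ratio was turned only in the test of a mixture of RNA; in comparisons of groups this would exchange higher and lower and keep each count. The check on known genes meant to decide it and the alternatives on gene lists were not run, since the spots carry no gene names. The ratios carry no signal over background, so no limit from depth can be stated.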

Other observations

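The tests of slide position, of a shared gene and of neighbouring genes were chosen after the result was seen, as were the offsets and the grouping by level; the test of a level trend was not.

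Spot pairs whose numbers differ by 2304 changed together. At 120 min their KCl effects correlated at r = 0.585 over 1463 couples, where 1000 shuffles of the spot pairs gave at most 0.0858 in size, and the next highest of the offsets up to 4000 gave 0.287, at 2324. Of 446 couples with both members changed, 389 (87.2%) changed the same way, where independent directions would give 228. The correlation was 0.486 at 30 min, 0.573 at 60 min, 0.595 at 240 min and 0.169 at 0 min. It was 0.328 in the untreated course from 0 to 240 min, with 0.197 of the covariance at 120 min, so a correlation at this offset was not confined to KCl effects. In the untreated course, however, it was less particular to this offset. There offsets of 1, 2 and 18 gave 0.201, 0.174 and 0.189, 2324 gave 0.232 and 288 gave 0.0683. Levels were alike as well as changes. Spots 6912 apart, a first copy and the second copy of the spot pair 2304 on, correlated at 0.56 in their mean log ratios.

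A position effect on the slide that varies between the arrays of a group is argued against, since the spread within any of the 10 groups accounts for at most 0.0683 of the covariance at 120 min. One shared by the arrays of a group stays open: the layout is not given in the sources used here, and offsets of 4, 16 and 20 gave 0.168, 0.148 and 0.235, where 1, 2, 18 and 288 gave 0.0174, -0.0153, -0.0150 and 0.0145. The median difference between first and second copies also differed between the groups at 120 min, -0.33 to -0.30 with KCl and -0.13 to 0.10 without. Centring the copies separately left the correlation at 0.584. A trend of the change with level is argued against as well, since the correlation stayed at 0.579 once that trend was removed. The same gene under 2 probes stays open. The copies of a spot pair correlated at 0.964 in their effect, but they are copies of 1 probe. They do not show how closely 2 probes of 1 gene would agree. The partner was called in the same direction for 346 (70.0%) of 494 members changed by at least 1 on the log2 scale at 120 min. Of all 3205 tested spot pairs, 912 were called higher and 674 lower at that time. For 191 (38.7%) of the 494 members, however, the change of the partner was well below that of the member. Since the agreement of 2 probes of 1 gene is not known here, neither count decides the question. Another candidate explanation is that neighbouring genes transcribed together were printed 2304 apart. The 0.585 cannot tell it apart from a shared gene or from other rules of layout, because the spots carry no gene names.

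Spot pairs were also grouped by their ratio in untreated cells at 0 min. The 25% with the lowest ratio (802 spot pairs) had median changes of 0.02, 0.32, 0.22 and 0.13 at 30, 60, 120 and 240 min, and the 25% with the highest ratio (801 spot pairs) 0.13, 0.06, 0.05 and 0.15. These medians depended on the processing. Quantile normalization gave 0.07, 0.19, 0.14 and 0.14 for the low group and -0.12, -0.16, -0.13 and -0.09 for the high group, and the values as deposited gave -0.16, -0.07, 0.06 and -0.27, and -0.05, -0.34, -0.10 and -0.25. At 120 min the low group was at 0.05 on the first copies alone and 0.37 on the second, and at 0.23 with the copies centred separately. Since the medians moved with the processing, no direction is stated for either group. Camera with a preset correlation of 0.01, run on the 2955 spot pairs with a value on all arrays, gave the low group an FDR of 3.07e-04 at 60 min, with an adjusted p of 0.204 with an estimated correlation. At 30 min the high group and the second lowest group each had an FDR of 0.0403, with 0.478 and 0.0831 with an estimated correlation. In the untreated course the low group had 0.0178, with 0.521 with an estimated correlation. The arrays that formed the groups are also the 0 min arrays of that course. Noise that puts a spot pair in the low group thus also raises its change, and nothing is concluded from that value. No group passed at any of the 4 times with an estimated correlation.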
